A study of Mus musculus with 13 samples.

How the data were processed

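The series measured RNA by sequencing in 13 libraries of wild-type FvB mice. Of these, 5 were ventricles at embryonic day (E) 17 and postnatal days (PN) 1, 10, 28 and 90. The other 8 were isolated cells: 4 cardiomyocyte libraries (2 neonatal, PN30 and PN67) and 4 cardiac fibroblast libraries (2 neonatal, PN28 and PN60). Per the labels' protocols, atria were removed in every case. Neonatal cardiomyocytes were obtained by preplating, in which fibroblasts attach to a dish before cardiomyocytes do, and PN30 and PN67 cardiomyocytes by Langendorff perfusion, in which enzymes are passed through the coronary vessels. Stage and isolation method therefore could not be told apart in cardiomyocytes. Fibroblasts of every stage were isolated by preplating after enzymatic digestion, per the labels. RNA of ventricles and cardiomyocytes was extracted with a kit for fibrous tissue and RNA of fibroblasts with a kit for small samples. Ventricle libraries were made from RNA depleted of ribosomal RNA and cell libraries with a TruSeq protocol, so the ratios of ventricle to cell levels in the closing section hold this difference as well.

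The deposited values were FPKM (fragments per kilobase of transcript, scaled to library size) of 94696 transcripts per library, in the isoform format of Cufflinks. TopHat2 2.0.5, Cufflinks 2.1.1 and the mouse build mm9 are named per the submitters' processing notes, and the annotation release is not given in the sources used here. FPKM divides by transcript length and library size, and Cufflinks shares fragments among overlapping isoforms by an estimate, so isoforms that differ little are poorly resolved and genes with near-identical copies, such as ribosomal protein genes and their pseudogenes, are uncertain. The deposited tables also held a coverage value, 95% confidence bounds of FPKM and a status per transcript. Total fragment counts are not given in these tables. The median ratio of the deposited coverage to FPKM, which rises with depth, was between 19.6 and 32.8 over the 13 libraries. The median half-width of the confidence interval of FPKM was between 3.93% and 5.06% of the value.

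Transcripts with a status of HIDATA (17 to 98 per library) or FAIL (54 to 198 per library) were listed at an FPKM of 0. Their genes were left out, 90 of them in the cell libraries and 64 in the ventricles, since a sum over the other transcripts would be too low. The plan had been to sum the transcripts with status OK, and leaving out the whole gene was decided when the zeros were seen. Myh6 in all libraries, Myh7 in ventricles and Postn in the cell libraries are not analysed here for this reason. The same holds in all libraries for many mitochondrially encoded genes, such as mt-Co1, mt-Atp6 and mt-Nd1. Transcripts shorter than 200 nucleotides were left out, because some of them had very large FPKM values in ventricles. Transcript identifiers were matched to GENCODE release M21 for gene and isoform names only (82379 of 94696, 87.0%). Unmatched transcripts held between 6.59% and 9.97% of the FPKM of a library. Coordinates are those of the deposited tables in mm9, counted from 1.

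Gene FPKM was the sum over the kept transcripts of a gene. Transcripts with a status of LOWDATA in any library of a set were left out of this sum. Such transcripts numbered 3646 to 3655 per library among all deposited ones, so some sums are partial. Libraries were scaled by the median of their ratios to the geometric mean over genes, separately for the 8 cell libraries and the 5 ventricle libraries. Genes with a mean FPKM of at least 1 were tested (12095 in cells, 11635 in ventricles) on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (empirical Bayes with an intensity trend) and Benjamini-Hochberg adjustment. A gene was called at an adjusted p below 0.05. Fold changes are on this log2 scale, which understates the change of genes with low FPKM. Count-based tests were not used because the values are not counts. The cell fit had 4 classes (cell type by stage, neonatal or later), with 4 residual degrees of freedom. The later class of a cell type held its 2 later ages, because none of these had a replicate, so the difference between the ages was part of the error. Its contrasts were later minus neonatal in each cell type, the difference of these changes, and cardiomyocytes minus fibroblasts averaged over the stages. The ventricle fit was a slope on the order of the 5 stages with 3 residual degrees of freedom. All tests were two-sided.

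Isoform use was tested with limma on log2 of the ratio of an isoform to the other isoforms of its gene, with 0.5 added to each. An isoform was called at an adjusted p below 0.05 and a change of its share of at least 10 percentage points. Genes had a mean FPKM of at least 5 and at least 1 in every library, and isoforms a mean share from 5% to 95%. For isoforms, genes with a transcript of any status other than OK, LOWDATA included, were left out. The 27 gene lists, which included markers of other cell types, were fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. Lists with at least 5 measured members were tested with camera at a preset correlation of 0.01 and again with an estimated correlation. Of the 735 list entries, 11 had no match and are not analysed here, and others were left out for their status or by the filter on FPKM, so counts are given out of the measured members.

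Named genes were the 5 largest rises and the 5 largest falls per comparison among called genes with a mean FPKM of at least 10, predicted genes excepted, the 3 called members with the largest moderated statistic of each list that passed, and a short set of heart genes chosen beforehand. Some of them are not reported here. The 3 erythroid markers of the cell libraries were added after their values were seen. Named isoforms were the 5 genes with the largest change of share per comparison and called members of the vesicular trafficking and splicing regulator lists.

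The procedure was tested on simulated data, with 200 changed genes or isoforms per comparison. The noise was normal and independent between genes, and ventricle changes had equal steps. In the data many more genes were called and genes were correlated, so these rates need not carry over. At a true log2 change of 1, it recovered 83% of changed genes for the cardiomyocyte stage change, 87% for fibroblasts, 29% for the difference between cell types, 98% for cell type and 13% for the ventricle trend from E17 to PN90. At a change of 2 these were 100%, 98%, 97%, 100% and 84%. For isoform ratios, 54% (cardiomyocytes), 53% (fibroblasts) and 0% (ventricles) were recovered at a change of 1, and 99%, 96% and 58% at a change of 2. False calls made up between 3.08% and 9.41% of all calls in these runs.

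The alternatives were the FPKM as deposited, removal of mitochondrially encoded genes with equal sums, a pseudocount of 0.1, other filters on low FPKM, other groupings of ages and stages, other thresholds for isoforms, and leaving out each library in turn. Many mitochondrially encoded genes had already been left out for their status. In the cell libraries, their removal with equal sums therefore mainly changed the scaling (12082 genes tested, against 12087 as deposited). Alternatives added after the data were seen are named in the closing section. Figures and tables were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.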

Results

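RNA was measured in 5 ventricle libraries (E17, PN1, PN10, PN28 and PN90, 1 library each), 4 cardiomyocyte libraries (2 neonatal, PN30 and PN67) and 4 cardiac fibroblast libraries (2 neonatal, PN28 and PN60). Cardiomyocytes are the contracting muscle cells of the heart, and cardiac fibroblasts make its connective tissue. The design addressed how gene expression and isoform use changed from birth to adulthood in whole ventricles and in each cell type. The neonatal labels covered PN1 to PN2 and PN1 in cardiomyocytes, and PN1 to PN3 and PN1 to PN2 in fibroblasts. Each library listed between 19335 and 23323 transcripts with an FPKM of at least 1. The ratio of coverage to FPKM, which rises with depth, was 19.6 to 25.1 in ventricles, 21.8 to 25.2 in cardiomyocytes and 30.4 to 32.8 in fibroblasts, so fibroblasts were measured most deeply. The neonatal replicates correlated with Spearman's rho of 0.993 across 12095 genes in cardiomyocytes and 0.989 in fibroblasts, where genes are not independent replicates. All other ages and all ventricle stages had no replicate. Nothing in the labels says that the neonatal libraries came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical. A comparison of 2 against 2 libraries cannot reach a p of 0.05 by permutation, and the tests drew on the spread over all genes and libraries through limma.

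Cardiomyocytes and fibroblasts were first compared with each other over both stages. The myosin light chains Myl3 and Myl2, cardiac troponin T (Tnnt2), muscle creatine kinase (Ckm) and mitochondrial creatine kinase (Ckmt2) had the largest excess in cardiomyocytes. Their log2 differences were 7.04 ± 0.09 (SE), 6.73 ± 0.12, 6.74 ± 0.10, 6.78 ± 0.10 and 6.99 ± 0.14. Tnfaip6 (-6.50 ± 0.09), the pentraxin Ptx3 (-6.45 ± 0.15) and the chemokines Ccl7 (-6.24 ± 0.16), Cxcl2 (-5.99 ± 0.26) and Cxcl3 (-5.71 ± 0.30) had the largest excess in fibroblasts. All 10 had limma adjusted p-values of at most 1.82e-06. All 14 measured cardiomyocyte markers were higher in cardiomyocytes (median log2 difference 6.63). All 11 fibroblast markers (median -3.11) and all 31 matrix genes (median -2.55) were higher in fibroblasts. Genes of oxidative phosphorylation, the respiratory chain and ATP synthase of mitochondria, were higher in cardiomyocytes for 51 of 51 members (median 3.27). So were 29 of 30 genes of fatty acid oxidation (median 3.96) and all 19 of the tricarboxylic acid cycle (median 3.31). Of 50 cytoplasmic ribosomal protein genes, 47 were higher in fibroblasts (median -0.55), and Ptbp1, a repressor of splicing, had a log2 difference of -1.97 ± 0.19 (adjusted p = 4.26e-05). Camera gave adjusted p-values of at most 3.86e-06 for these lists, against adjusted p-values from 0.214 to 0.339 with an estimated correlation.

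Markers of other cell types were present in both preparations. Of 15 macrophage and leukocyte markers, 12 were higher in fibroblasts and 0 in cardiomyocytes (median -0.91, camera adjusted p = 0.0113, and adjusted p = 0.449 with an estimated correlation). Of 13 endothelial markers, 9 were higher in cardiomyocytes and 1 in fibroblasts (median 0.75, camera adjusted p = 0.0483, and adjusted p = 0.449 with an estimated correlation). Smooth muscle and pericyte markers were higher in cardiomyocytes for 6 of 9 and lower for 1 (camera adjusted p = 0.0713). Mesothelial and epicardial markers split into 4 higher and 2 lower of 9 (camera adjusted p = 0.679). In the neonatal fibroblast libraries, cardiomyocyte markers stood at a median of 10.1% and 8.80% of their level in cardiomyocytes, against 0.0648% and 0.0637% at PN28 and PN60. Fibroblast markers stood in neonatal cardiomyocytes at a median of 11.2% of their level in neonatal fibroblasts, with a range from 6.57% to 22.8% over 11 markers. In later cardiomyocytes the median was 12.6% of the level in later fibroblasts, from 4.11% to 21.9%. Erythroid markers had too few measured members for a list test. All 3 of them, named after their values were seen, fell in cardiomyocytes, Hba-a2 from 11059.8 to 637 and 382 FPKM (log2 change -4.47 ± 0.39, SE), Hbb-bt by 4.13 and Alas2 by 4.27 (adjusted p at most 0.000105), and none was called in fibroblasts (adjusted p at least 0.450). In all, 9275 of 12095 genes differed, 4494 higher in cardiomyocytes and 4781 higher in fibroblasts, and with mitochondrial genes removed the split was 3869 and 5586. A fit of cell type without stage called 4542 genes.

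**Figure D1:**
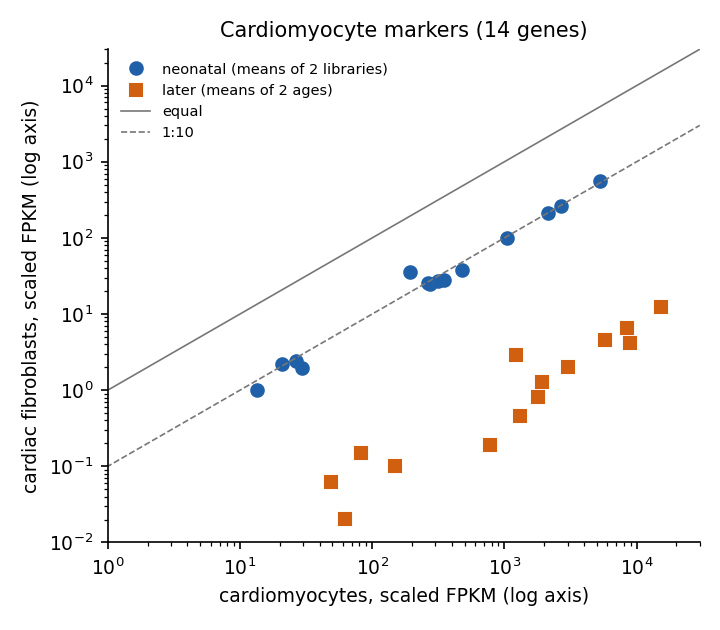
Scaled FPKM of 14 cardiomyocyte markers in cardiac fibroblasts against cardiomyocytes, both on log axes, as means of the 2 neonatal libraries and of the 2 later ages, with lines at equal levels and at 1:10. The neonatal points lie near the 1:10 line, with medians of 10.1% and 8.80% in the 2 fibroblast libraries, and the later points lie far below it.

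In cardiomyocytes, the slow skeletal isoform of troponin I, Tnni1 (chromosome 1, 137679642 to 137707566 in mm9), fell from 715 ± 61.8 FPKM (SD, n = 2) in neonatal cells to 0.637 at PN30 and 0.150 at PN67. The cardiac isoform Tnni3 rose from 1049 ± 161 to 5890.2 and 5705 FPKM. The log2 changes were -9.03 ± 0.18 (SE, limma adjusted p = 6.05e-07) and 2.47 ± 0.17 (adjusted p = 2.06e-05). The largest rise was that of Art1, an ADP-ribosyltransferase (chromosome 7, 109250257 to 109259662), from 0.917 ± 0.109 to 172 and 176 FPKM. It was followed by the carboxylesterase Ces1d (log2 change 6.02 ± 0.39), the muscle ribosomal protein Rpl3l (5.96 ± 0.14), Ckmt2 (5.55 ± 0.19) and the tubulin Tuba8 (5.43 ± 0.16). Ces1d belongs to a family of similar genes and its value is uncertain. After Tnni1, the largest falls were those of the imprinted RNA H19 (-5.84 ± 0.34), heme oxygenase Hmox1 (-5.81 ± 0.50), the xenobiotic enzyme Cyp1a1 (-5.67 ± 0.47) and the adhesion molecule Icam1 (-5.49 ± 0.23), all with adjusted p-values of at most 5.00e-05.

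Genes of energy metabolism rose together in cardiomyocytes. All 51 measured members of oxidative phosphorylation rose (median log2 change 1.86, 51 when adjusted over the list alone). Cox7a1, the heart and muscle subunit of cytochrome oxidase, rose from 327 ± 7.18 (SD, n = 2) to 4124 and 4129 FPKM, Sdhb by 2.30 ± 0.10 (SE) and Ndufb9 by 2.05 ± 0.10. All 19 members of the tricarboxylic acid cycle rose (median 2.12, 19 adjusted over the list alone), among them Ogdh (2.98 ± 0.13) and Idh3b (2.23 ± 0.10). Of 30 genes of fatty acid oxidation, 27 rose and 3 did not pass (median 1.94, 27 adjusted over the list alone). Hadhb rose from 237 ± 1.51 to 1442 and 1692 FPKM, Echs1 by 2.82 ± 0.15 and Etfa by 2.21 ± 0.11. In glycolysis, 11 of 18 rose and 3 fell (11 and 3 adjusted over the list alone), with rises of Aldoa (1.96 ± 0.10), Eno3 (2.1 ± 0.14) and Hk2 (3.06 ± 0.23). Camera gave adjusted p-values of 8.67e-17, 2.18e-08, 3.22e-08 and 0.0391 for these lists, each with an adjusted p = 0.391 with an estimated correlation.

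Contractile, calcium and channel genes rose for most members. All 14 cardiomyocyte markers rose (median 2.1, 14 adjusted over the list alone), including Myl3 from 2135 ± 68.2 (SD, n = 2) to 9558 and 8323 FPKM, Mybpc3 by 2.26 ± 0.13 (SE) and Tnnt2 by 1.65 ± 0.14. In the sarcomere and Z-disc list, 30 of 35 rose and 4 fell (30 and 4 adjusted over the list alone), with Xirp2 (4.16 ± 0.17) and Cmya5 (4.10 ± 0.16) among the rises and Tnni1 among the falls. Myh7, the beta myosin heavy chain, rose by 1.49 ± 0.17 from 204 ± 38.5 to 571 and 568 FPKM. Myh6, another myosin heavy chain, had no usable value in the first neonatal, PN30 and PN67 cardiomyocyte libraries. Myh6 and Myh7 could therefore not be compared, and the rise of Myh7 is uncertain where this related gene had no value. In ventricles, Myh7 had a status of HIDATA at E17 and PN1 only and was left out, so its rise could not be checked there. Genes of calcium handling, which couple excitation to contraction, rose for 14 and fell for 4 of 24 (14 and 4 adjusted over the list alone). Among them were Hrc (4.05 ± 0.12), Pln, the inhibitor of the calcium pump of the sarcoplasmic reticulum (3.27 ± 0.10), and Tmem38a (2.78 ± 0.15). Ion channels and gap junctions rose for 21 and fell for 4 of 27 (21 and 4 adjusted over the list alone), with the potassium channel genes Kcnip2 (3.32 ± 0.14), Kcnd2 (2.89 ± 0.17) and Kcnj12 (2.38 ± 0.14). Camera adjusted p-values were 1.86e-06 for the markers, 9.00e-08 for the sarcomere, 0.00647 for calcium handling and 0.000925 for channels. With an estimated correlation the adjusted p was 0.391, 0.391, 0.411 and 0.411.

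Genes of proliferation, fetal growth and translation fell in cardiomyocytes. Of 41 cell cycle genes, 40 fell (median -2.11, 41 adjusted over the list alone). Rrm2 fell from 21.0 ± 0.967 (SD, n = 2) to 2.51 and 1.71 FPKM, and the log2 changes of Birc5, Ect2 and the proliferation marker Mki67 were -2.97 ± 0.19 (SE), -2.16 ± 0.13 and -2.73 ± 0.35. Of 17 imprinted and fetal growth genes, 16 fell (median -2.02, 16 adjusted over the list alone), with the growth factor Igf2 from 578 ± 23.2 to 27.2 and 12.5 FPKM, Plagl1 (-4.87 ± 0.21) and Dlk1 (-3.62 ± 0.22). Ribosomal protein genes fell for 49 of 50 (median -0.90, 49 adjusted over the list alone), among them Rpl3 (-1.88 ± 0.10), Rps24 (-2.37 ± 0.15) and Rpl24 (-2.50 ± 0.15), with the limit that pseudogene copies can share their reads. Of 44 splicing regulators, 27 fell and 8 rose (median -0.72, 27 and 8 adjusted over the list alone, or 32 and 5 as deposited). Ptbp1 (-2.64 ± 0.27), Tra2b (-1.67 ± 0.12) and Hnrnpa1 (-1.51 ± 0.10) fell and Rbfox1 (2.04 ± 0.12) rose. In this order of lists, camera gave adjusted p-values of 2.29e-14, 2.96e-07, 1.46e-14 and 0.00116, and with an estimated correlation the adjusted p was 0.391, 0.225, 0.391 and 0.391. The splicing factor Celf1 fell by a log2 change of -0.42 ± 0.14 (adjusted p = 0.0263). Without the first or second neonatal or the PN67 cardiomyocyte library its changes were -0.42, -0.43 and -0.35, with limma adjusted p-values of 0.103, 0.105 and 0.126.

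Genes of matrix, activation and stress also fell in cardiomyocyte libraries. Of 31 matrix genes, 20 fell and 3 rose (median -0.82, 20 and 3 adjusted over the list alone). Fibronectin Fn1 fell from 38.9 ± 0.253 (SD, n = 2) to 1.55 and 0.409 FPKM, and Col12a1 (-2.75 ± 0.16, SE) and the cross-linking enzyme Lox (-2.56 ± 0.13) fell too. Fibroblast markers stood in neonatal and later cardiomyocytes at a median of 11.2% and 12.6% of their fibroblast level, and this share was not subtracted. Fn1 fell in fibroblasts as well, so falls of matrix and myofibroblast genes here may hold a fall in fibroblast RNA, which was not tested. The collagen Col1a1 fell with a log2 change of -1.30 ± 0.37 (adjusted p = 0.0155), or -1.16 with an adjusted p of 0.0829 without the first neonatal cardiomyocyte library. Genes of myofibroblast activation fell for 16 of 17 (median -2.20, 16 adjusted over the list alone), including Actg2 (-3.01 ± 0.17) and Cthrc1 (-3.16 ± 0.19). Of 26 immediate early and stress genes, 11 fell, 0 rose and 15 did not pass (median -1.28, 11 adjusted over the list alone), while 18 fell with the FPKM as deposited and 19 with mitochondrial genes removed, with Myc from 80.1 ± 0.662 to 1.76 and 3.32 FPKM and Klf6 (-3.05 ± 0.27). Endothelial markers fell for 11 and rose for 1 of 13 (median -1.02, 11 and 1 adjusted over the list alone), with Cldn5 (-4.02 ± 0.14), Cdh5 (-1.94 ± 0.16) and Pecam1 (-1.57 ± 0.15). The camera test gave adjusted p-values of 0.00162 for matrix, 7.88e-07 for myofibroblast activation, 8.48e-05 for immediate early genes and 0.000816 for endothelial markers. With an estimated correlation the adjusted p was 0.391, 0.225, 0.411 and 0.391.

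Other lists did not pass in cardiomyocytes. Fibroblast markers had 6 up and 4 down of 11 (median 0.35, camera adjusted p = 0.644), and 4 up and 4 down with the FPKM as deposited. Vesicular trafficking genes, which act in transport between membranes, had 35 up and 25 down of 97 (33 and 25 adjusted over the list alone, camera adjusted p = 0.907), which turned to 23 up and 38 down with the FPKM as deposited. Atrial markers were called down for 6 and up for 1 of 9 (camera adjusted p = 0.0652). The natriuretic peptide Nppa among them fell with a log2 change of -2.13 ± 0.66 (SE, adjusted p = 0.0225). Without the first neonatal, the PN30 and the PN67 cardiomyocyte library its change was -1.06, -1.91 and -2.34 (limma adjusted p = 0.110, 0.104 and 0.0592). Macrophage markers were called up for 9 and down for 2 of 15 (camera adjusted p = 0.118) and complement and chemokine genes up for 10 and down for 2 of 15 (adjusted p = 0.118). Mesothelial markers were called down for 5 of 9 (adjusted p = 0.0772) and smooth muscle markers up for 3 and down for 3 of 9 (adjusted p = 0.588). Matrix proteases were called up for 4 and down for 6 of 18 (or 1 and 8 as deposited, adjusted p = 0.295) and fetal muscle genes up for 5 and down for 7 of 15 (adjusted p = 0.402).

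In all, 8135 of 12095 genes changed in cardiomyocytes, 4467 up and 3668 down, and 2580 rose and 1859 fell at least 2-fold. With the FPKM as deposited the split was 3363 up and 4867 down. With mitochondrial genes removed and libraries scaled to equal sums it was 3003 up and 5227 down. These scalings moved the median change of all genes from 0.09 to -0.18 and -0.26.

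**Figure D2:**
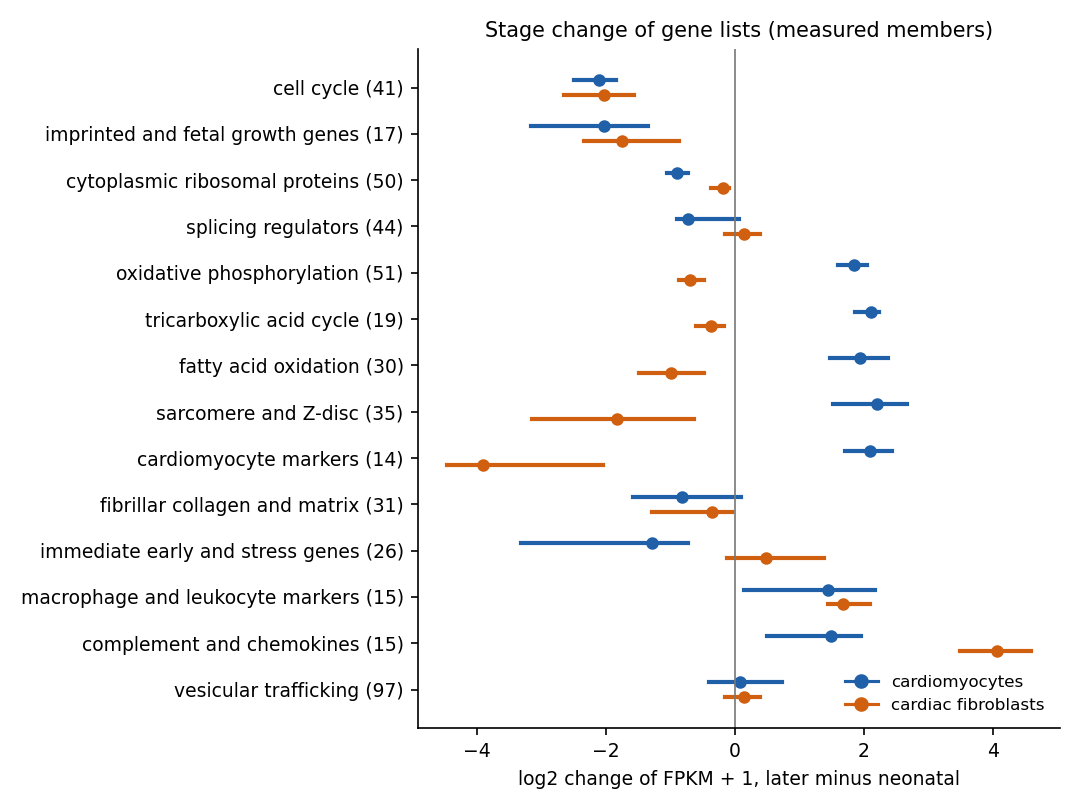
Log2 change of FPKM + 1 from neonatal to later cells for 14 gene lists in cardiomyocytes and cardiac fibroblasts, with points at the median over the measured members and bars over the middle 50% of members. Oxidative phosphorylation had a median of 1.86 in cardiomyocytes and -0.69 in fibroblasts, while cell cycle genes had medians of -2.11 and -2.04, and the splits of trafficking genes in both cell types and of splicing regulators in fibroblasts turned under the other scalings.

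In cardiac fibroblasts, the cytokine interleukin 6 (Il6, chromosome 5, 30339701 to 30346508) rose from 7.09 ± 3.76 FPKM (SD, n = 2) in neonatal cells to 2873 at PN28 and 2955 at PN60, a log2 change of 8.58 ± 0.33 (SE, limma adjusted p = 9.17e-06). In PN28 and PN90 ventricles, whose libraries were made with another kit, Il6 had a mean of 0.0111 FPKM. The growth factor Csf2 (7.09 ± 0.54), the chemokine Cxcl5 (6.85 ± 0.38), Retnla (6.27 ± 0.13) and the lubricating proteoglycan Prg4 (5.97 ± 0.24) were the next largest rises. H19 (chromosome 7, 149761434 to 149764048) fell from 1755 ± 554 to 3.65 and 5.09 FPKM (-8.33 ± 0.34) and Dlk1, an inhibitor of differentiation, from 63.0 ± 10.6 to 0.207 and 0.319 FPKM (-5.65 ± 0.22). The other largest falls were those of the muscle genes Tnni1 (-5.95 ± 0.18), Myl2 (-5.40 ± 0.16) and Myl3 (-5.34 ± 0.13). Myl2 stood at 552 ± 44.3 FPKM in neonatal fibroblasts and at 5303 in neonatal cardiomyocytes.

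Complement, chemokine and macrophage genes rose in fibroblasts. Of 15 complement and chemokine genes, 14 rose (median log2 change 4.07, 15 adjusted over the list alone), including Ccl8 from 0.0318 ± 0.00153 (SD, n = 2) to 48.8 and 67.9 FPKM. Of 15 macrophage and leukocyte markers, 13 rose and 1 fell (median 1.67, 13 and 1 adjusted over the list alone). Lyz2 rose from 50.2 ± 23.5 to 446 and 394 FPKM, Cd14 by 2.60 ± 0.29 (SE) and Ptprc, the pan-leukocyte marker, by 2.02 ± 0.16. Immediate early and stress genes rose for 8 and did not pass for 18 of 26 (median 0.49, 8 adjusted over the list alone), with Socs3 (2.99 ± 0.53), Gadd45b (2.35 ± 0.41) and Ier3 (2.28 ± 0.18). Camera adjusted p-values were 3.09e-11, 3.14e-05 and 0.0313, with an adjusted p of 0.316, 0.393 and 0.591 with an estimated correlation. With the cardiomyocyte share subtracted, the immediate early list did not pass (camera adjusted p = 0.0915), with 8 up and 0 down as before and a median of 0.43.

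Proliferation and fetal growth genes fell in fibroblasts. Of 41 cell cycle genes, 39 fell (median -2.04, 40 adjusted over the list alone). Ccnb1 fell from 9.74 ± 0.240 (SD, n = 2) to 0.502 and 0.206 FPKM, and Rrm2 (-2.65 ± 0.18, SE), Ect2 (-2.48 ± 0.13) and Mki67 (-1.86 ± 0.35) fell too. Imprinted and fetal growth genes fell for 15 and rose for 2 of 17 (median -1.75, 15 and 2 adjusted over the list alone), with Igf2 from 831 ± 199 to 35.4 and 31.0 FPKM and Igf2bp1 (-2.40 ± 0.14). Of 31 matrix genes, 10 fell, 4 rose and 17 did not pass (median -0.36, 11 and 4 adjusted over the list alone), while 15 fell and 3 rose as deposited and 16 fell with mitochondrial genes removed. Fn1 fell from 246 ± 12.3 to 10.9 and 6.95 FPKM, as did Fbn2 (-3.38 ± 0.22), Col1a2 (-1.46 ± 0.16) and Col1a1 (-1.95 ± 0.37). Mesothelial and epicardial markers fell for 8 of 9 (median -1.30, 9 adjusted over the list alone), among them Aldh1a2 (-1.46 ± 0.19), Wt1 (-1.82 ± 0.26) and Tbx18 (-1.01 ± 0.19). Endothelial markers fell for 8 of 13 (median -0.82, 8 adjusted over the list alone), with Kdr (-1.48 ± 0.11), Emcn (-1.70 ± 0.23) and Tie1 (-1.63 ± 0.20). Camera adjusted p-values were 4.52e-19 for cell cycle, 1.21e-06 for imprinted genes, 0.0469 for matrix, 0.00139 for mesothelial and 0.00139 for endothelial markers. With an estimated correlation the adjusted p was 0.330, 0.316, 0.553, 0.393 and 0.393.

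Muscle and mitochondrial genes fell in fibroblasts, in libraries where cardiomyocyte markers stood at 10.1% and 8.80% (neonatal) and 0.0648% and 0.0637% (PN28 and PN60) of their level in cardiomyocytes. All 14 cardiomyocyte markers fell (median -3.91, 14 adjusted over the list alone), with Tnnt2 from 262 ± 20.1 (SD, n = 2) to 5.90 and 7.23 FPKM and Actn2 (-4.47 ± 0.13, SE). Of 35 sarcomere genes, 27 fell and 1 rose (27 and 1 adjusted over the list alone). Fetal muscle genes fell for 12 of 15 (13 adjusted over the list alone), including Myh7 (-4.50 ± 0.17) and Ankrd1 (-3.16 ± 0.36). Calcium handling genes fell for 9 of 24 (9 adjusted over the list alone), including Pln (-3.23 ± 0.10), Ryr2 (-1.43 ± 0.16) and Hrc (-1.01 ± 0.12). Of 51 oxidative phosphorylation genes, 45 fell (median -0.69, 45 adjusted over the list alone), with Cox6a2 (-3.90 ± 0.16), Cox8b (-3.14 ± 0.14) and Cox7a1 (-2.15 ± 0.19). Fatty acid oxidation genes fell for 20 and rose for 1 of 30 (median -0.99, 22 and 1 adjusted over the list alone), with Fabp3 from 151 ± 25.1 to 9.57 and 6.72 FPKM, Cpt1b (-2.35 ± 0.15) and Acads (-1.46 ± 0.12). Genes of the tricarboxylic acid cycle fell for 9 and rose for 1 of 19 (median -0.37, 11 and 1 adjusted over the list alone), with Idh2 (-3.25 ± 0.23) and Cs (-0.88 ± 0.12), and 16 fell with the FPKM as deposited. In this order of lists, camera gave adjusted p-values of 5.12e-13, 5.12e-13, 3.45e-06, 0.00574, 7.45e-13, 6.06e-07 and 0.00620. With an estimated correlation the adjusted p was 0.316, 0.330, 0.330, 0.424, 0.352, 0.393 and 0.548. After the cardiomyocyte share was subtracted, an alternative chosen after seeing the data, none of these lists passed (camera adjusted p from 0.0833 for the markers to 0.850). Calls were then 6 up and 9 down in oxidative phosphorylation, 6 up and 5 down in fatty acid oxidation and 6 up and 2 down in the tricarboxylic acid cycle (median 0.18). For the cardiomyocyte markers, whose median set the share subtracted, the loss followed from the subtraction itself. Calls were 5 and 5 in the sarcomere, 2 and 4 in fetal muscle and 2 and 1 in calcium handling.

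Of the remaining lists, the ribosomal protein genes passed in fibroblasts. Ribosomal protein genes fell for 13 and rose for 1 of 50 (median -0.19, 11 and 0 adjusted over the list alone, camera adjusted p = 0.00213, and adjusted p = 0.591 with an estimated correlation), and 45 fell with the FPKM as deposited. Rpsa (-0.48 ± 0.09, SE), Rps7 (-0.47 ± 0.09) and Rps29 (-0.45 ± 0.09) fell. Without the second neonatal fibroblast library their changes were -0.45, -0.44 and -0.39, with limma adjusted p-values of 0.0514, 0.0577 and 0.0766. Splicing regulators were called up for 11 and down for 7 of 44 (camera adjusted p = 0.193) and trafficking genes up for 20 and down for 16 of 97 (adjusted p = 0.177). These turned to 5 up and 13 down and to 6 up and 30 down with the FPKM as deposited. Glycolysis genes were called up for 5 and down for 3 of 18 (adjusted p = 0.425), or 4 and 6 as deposited, and with the cardiomyocyte share subtracted 8 and 0 (adjusted p = 0.0417, and adjusted p = 0.614 with an estimated correlation). Fibroblast markers were called up for 4 and down for 2 of 11 (median 0.14, camera adjusted p = 0.344), with a median of -0.20 as deposited. Ion channels (2 up and 11 down of 27, adjusted p = 0.0889), atrial markers (0 and 2 of 9, or 0 and 4 as deposited, median -0.97, 0.0792) and smooth muscle markers (2 and 2 of 9, or 2 and 4 as deposited, 0.894) did not pass. Nor did myofibroblast activation (3 up and 6 down of 17, or 2 and 10 as deposited, adjusted p = 0.110) and matrix proteases (5 and 3 of 18, or 4 and 4 as deposited, 0.0950). Ptbp1 had a log2 change of -0.14 ± 0.27 (adjusted p = 0.696), or -0.61 with an adjusted p of 0.00711 without PN60. Celf1 had one of -0.40 ± 0.14 (adjusted p = 0.0506), or -0.55 with an adjusted p of 0.0132 without PN28 and -0.73 with 0.00342 with the FPKM as deposited.

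In all, 4973 of 12095 genes changed in fibroblasts, 2382 up and 2591 down, and 1120 rose and 931 fell at least 2-fold. With the FPKM as deposited the split was 1474 up and 4656 down and with mitochondrial genes removed 1489 up and 4703 down. The median change of all genes moved from -0.03 to -0.29 and -0.30. The count was 2769 without the second neonatal fibroblast library and 3209 when only the 4 fibroblast libraries were fitted. No list call of camera held with an estimated correlation in any comparison, while 16 lists each passed with the preset correlation in cardiomyocytes, fibroblasts and ventricles. Genes that changed at least 2-fold had reached a median of 98.4% of their change by PN30 in cardiomyocytes (4439 genes) and 109% by PN28 in fibroblasts (2051 genes). PN30 and PN67 cardiomyocytes differed at least 2-fold for 2.21% of these genes, and PN28 and PN60 fibroblasts for 11.2%, with no replicate to test them. The fit counted the difference between the later ages as error, so that genes whose later ages differed were less often called and these shares do not describe all genes.

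The stage change differed between the cell types for 7124 of 12095 genes. The change was more positive in cardiomyocytes for 51 of 51 members of oxidative phosphorylation (median difference 2.50), 19 of 19 of the tricarboxylic acid cycle (2.50) and 29 of 30 of fatty acid oxidation (2.91). The same held for 14 of 14 cardiomyocyte markers (6.25) and 31 of 35 sarcomere genes (4.25), with 3 the other way. With the cardiomyocyte share subtracted from the fibroblast libraries, the median difference was 2.39 for the cardiomyocyte markers and 2.34 for the sarcomere, with 14 of 14 and 26 of 35 more positive. It was 1.93 for oxidative phosphorylation, 1.83 for the tricarboxylic acid cycle and 2.05 for fatty acid oxidation. Without the subtraction, camera adjusted p-values were at most 1.63e-09 for these lists, each with an adjusted p of at least 0.317 with an estimated correlation. Ribosomal protein genes had a more negative change in cardiomyocytes for 46 of 50 (median -0.73, camera adjusted p = 9.21e-11, and adjusted p = 0.427 with an estimated correlation), with Rpl3 at -1.50 ± 0.14 (SE). So did 15 of 26 immediate early and stress genes (median -2.38, camera adjusted p = 2.02e-05, and adjusted p = 0.427 with an estimated correlation), with Hmox1 at -7.85 ± 0.71 and Myc at -5.38 ± 0.30. Splicing regulators differed for 28 in this direction and for 6 in the other of 44 (median -0.72, camera adjusted p = 0.000375, and adjusted p = 0.427 with an estimated correlation), with Ptbp1 at -2.50 ± 0.38. Of 41 cell cycle genes, 35 showed no called difference (camera adjusted p = 0.737), among them Ect2 (0.32 ± 0.19) and Mki67 (-0.87 ± 0.50). Also without the subtraction, genes called in both cell types numbered 1909 with the same direction and 1529 with opposite directions. The overlap was 828 genes up in both, where independent lists would share 879.7, and 1081 down in both, where they would share 786.

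In ventricles, H19 fell from 4799 FPKM at E17 to 1669.5 at PN1, 260.1 at PN10, 33.8 at PN28 and 27.5 at PN90. Tnni1 fell from 741 and 782 at E17 and PN1 to 42.0, 0.418 and 0.281 at the later stages. Their slopes were -2.04 ± 0.18 (SE) and -2.75 ± 0.37 log2 units per stage (limma adjusted p = 0.00461 and 0.00576). Igf2 (-1.51 ± 0.10), the mitotic cyclin Ccnb1 (-1.57 ± 0.13) and Bex4 (-1.63 ± 0.28) were the other largest falls. The largest rises were those of Xirp2, an actin-binding protein of the intercalated disc (1.84 ± 0.20), Art1 (1.66 ± 0.22), Ces1d (1.64 ± 0.25), Ckmt2 (1.62 ± 0.23) and Rpl3l (1.61 ± 0.18). Ckmt2 rose from 25.6 FPKM at E17 to 129.7, 809, 1946 and 1911 at the later stages.

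**Figure D3:**
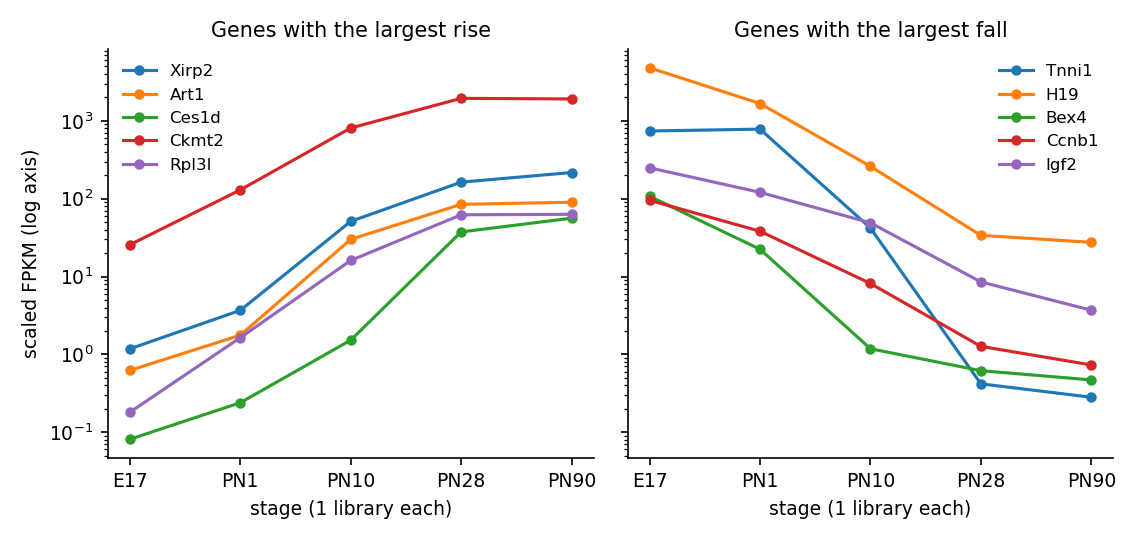
Scaled FPKM on a log axis at the 5 ventricle stages, 1 library each, for the 5 genes with the largest rise and the 5 with the largest fall. Tnni1 stood at 741 FPKM at E17, 0.418 at PN28 and 0.281 at PN90, and Ckmt2 at 25.6, 1946 and 1911.

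Cell cycle and fetal growth genes fell in ventricles, and metabolic and contractile genes rose. Of 42 cell cycle genes, 41 fell (median slope -1.06, 41 adjusted over the list alone), with Ube2c (-1.42 ± 0.12, SE), Cenpe (-1.13 ± 0.10) and Mki67 (-1.17 ± 0.15). All 16 imprinted and fetal growth genes fell (median -0.70, 16 adjusted over the list alone), with Peg3 (-0.94 ± 0.06) and Grb10 (-0.85 ± 0.06). Oxidative phosphorylation genes rose for 45 of 51 (median 0.37, 50 adjusted over the list alone), or 26 with the FPKM as deposited. Cox7a1 rose from 143 to 1637 FPKM, Ndufb3 by 0.43 ± 0.05 per stage and Ndufs4 by 0.43 ± 0.05. Fatty acid oxidation rose for 19 of 30 (median 0.47, 23 adjusted over the list alone), or 11 as deposited, with Ech1 (1.01 ± 0.06), Acot13 (0.51 ± 0.07) and Acadm (0.64 ± 0.09). The tricarboxylic acid cycle rose for 18 of 20 (median 0.30, 18 adjusted over the list alone), or 8 as deposited, with Ogdh (0.60 ± 0.07), Idh3b (0.46 ± 0.07) and Sucla2 (0.52 ± 0.08). Sarcomere genes rose for 23 and fell for 3 of 36 (26 and 3 adjusted over the list alone), or 17 and 4 as deposited and 15 and 3 with mitochondrial genes removed, with Tcap, a Z-disc protein (1.13 ± 0.06), Cmya5 (1.17 ± 0.13) and Lmod2 (0.83 ± 0.09). Ion channels rose for 13 and fell for 2 of 25 (15 and 3 adjusted over the list alone), with Kcnk3 (0.57 ± 0.08). In this order of lists, camera gave adjusted p-values of 3.05e-20, 1.54e-09, 3.69e-14, 2.50e-07, 1.37e-06, 1.47e-06 and 0.00173. With an estimated correlation the adjusted p was at least 0.488 for each.

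Markers of other cell types moved in ventricles as well. Macrophage and leukocyte markers rose for 12 of 13 (median 0.43, 12 adjusted over the list alone), with C1qc from 2.04 to 9.85 FPKM, C1qb by 0.53 ± 0.10 (SE) and Cd14 by 0.44 ± 0.08 per stage. Complement and chemokine genes rose for 9 of 12 (median 0.56, 9 adjusted over the list alone), with C1s1 by 0.59 ± 0.06 and C1ra by 0.60 ± 0.08. Mesothelial and epicardial markers fell for 8 of 9 (median -0.64, 9 adjusted over the list alone), with Upk3b (-0.94 ± 0.21), Msln (-0.61 ± 0.11) and Tbx18 (-0.51 ± 0.09). Matrix genes fell for 17 and rose for 3 of 38 (median -0.26, 18 and 3 adjusted over the list alone), with Fbn2 (-1.13 ± 0.09), Tnc (-0.76 ± 0.09) and Col12a1 (-0.63 ± 0.07). Myofibroblast genes fell for 10 and rose for 2 of 19 (10 and 2 adjusted over the list alone), with a fall of Myl9 (-0.84 ± 0.10). Splicing regulators fell for 19 and rose for 4 of 44 (27 and 4 adjusted over the list alone, or 30 and 2 as deposited), with Ptbp1 (-0.41 ± 0.04), Hnrnpd (-0.32 ± 0.05) and Rbfox1 (0.72 ± 0.10). In this order of lists, camera gave adjusted p-values of 8.31e-05, 0.000368, 0.000383, 0.000288, 0.00785 and 8.31e-05. With an estimated correlation the adjusted p was 0.488, 0.488, 0.488, 0.565, 0.488 and 0.488.

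Cardiomyocyte markers rose for 5 of 12 in ventricles (7 adjusted over the list alone, camera adjusted p = 0.00622, and adjusted p = 0.488 with an estimated correlation), with 2 up and 1 down with the FPKM as deposited. Tnni3 rose by 0.57 ± 0.11 (SE) per stage, Ryr2 by 0.53 ± 0.14 and Mybpc3 by 0.23 ± 0.06. The slope of Mybpc3 was 0.12 (limma adjusted p = 0.245) with the FPKM as deposited, and that of Ryr2 0.44 (adjusted p = 0.0690) with mitochondrial genes removed. Tnnt2 (0.27 ± 0.10, adjusted p = 0.0853), Nppa (-0.31 ± 0.33, adjusted p = 0.504) and Celf1 (-0.17 ± 0.06, adjusted p = 0.0694) did not pass. Celf1 passed with the FPKM as deposited (-0.27, adjusted p = 0.0184) and without PN90 (-0.26, adjusted p = 0.0413). Of 5 erythroid markers, 1 fell (0 adjusted over the list alone, and 3 fell as deposited, camera adjusted p = 0.0445, and adjusted p = 0.565 with an estimated correlation). This was Slc4a1 of red cells, from 25.4 FPKM at E17 to 1.10 at PN1 and 0.267 at PN90. Ribosomal protein genes fell for 4 of 50 (1 adjusted over the list alone, camera adjusted p = 8.31e-05, and adjusted p = 0.583 with an estimated correlation) and for 21 as deposited, with Rpl3 (-0.55 ± 0.07), Rps16 (-0.38 ± 0.08) and Rps24 (-0.27 ± 0.07). Col1a1 fell with a slope of -0.79 ± 0.20 and Postn, a matrix protein of fibroblasts, with -0.98 ± 0.25.

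The other lists did not pass in ventricles. Calcium handling genes (10 up and 2 down of 24, camera adjusted p = 0.0822), fetal muscle genes (0 and 4 of 12, 0.0822), atrial markers (0 and 3 of 9, 0.0987) and fibroblast markers (3 and 5 of 16, 0.585) were among them. So were matrix proteases (3 up and 5 down of 17, 0.403), glycolysis (3 and 4 of 19, 0.533) and immediate early genes (2 and 3 of 18, 0.915). Endothelial markers had 2 up and 0 down of 13 (adjusted p = 0.147), or 0 up as deposited. Smooth muscle markers had 3 up and 1 down of 9 (adjusted p = 0.603), or 2 and 3 as deposited. Trafficking genes had 15 up and 6 down of 95 (12 and 6 adjusted over the list alone, camera adjusted p = 0.180), or 7 and 16 as deposited.

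In all, 4092 of 11635 genes had a slope, 2212 up and 1880 down, and 1520 rose and 1181 fell at least 2-fold from E17 to PN90. With the FPKM as deposited the split was 1271 up and 3445 down and with mitochondrial genes removed 1266 up and 2889 down. The median slope of all genes moved from 0.00 to -0.09 and -0.08. The count was 1130 without E17, 2345 without PN1 and 2275 without PN28. Among the slopes that no longer passed without E17 were Bex4 (-1.24), Tnni3 (0.48), Ryr2 (0.28), Mybpc3 (0.19), Cd14 (0.46), C1qc (0.61), C1qb (0.57), Slc4a1 (-0.26), Tbx18 (-0.43), Msln (-0.40), Upk3b (-0.54), Acadm (0.49), Idh3b (0.41), Sucla2 (0.42), Kcnk3 (0.46), Hnrnpd (-0.30), Rps16 (-0.25), Rps24 (-0.20) and Col1a1 (-1.08). Without PN1, these were Ryr2 (0.55), Mybpc3 (0.25), Rps24 (-0.28), Col1a1 (-0.81) and Postn (-0.89). Without PN10 the only loss was Slc4a1 (-0.94). Those lost without PN28 were Tnni3 (0.54), Ryr2 (0.49), Mybpc3 (0.23), Slc4a1 (-0.92), Upk3b (-0.88), Rps24 (-0.24), Col1a1 (-0.80) and Postn (-0.88). Those lost without PN90 were Mybpc3 (0.23), Slc4a1 (-1.31), Rps16 (-0.43), Col1a1 (-0.47) and Postn (-0.85). Between neighbouring stages, 231 genes were at least 2-fold higher and 207 lower from E17 to PN1, 370 and 389 from PN1 to PN10, 386 and 310 from PN10 to PN28, and 54 and 59 from PN28 to PN90.

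The ventricle trend was then compared with the changes in isolated cells, over 10822 genes tested in both. Of the rising genes, 1753 also rose in cardiomyocytes, where independent lists would share 826. Of the falling genes, 1118 also fell, where they would share 485. Genes called in both had the same direction in 2871 cases and opposite directions in 147, so that 95.1% matched. With fibroblasts, 587 rising genes were shared, where independent lists would share 386, and 796 falling genes, where they would share 367. Of these genes, 1383 went in the same direction and 462 in opposite directions. The correlation of the ventricle slope with the stage change across genes, which are not independent replicates, was 0.723 for cardiomyocytes and 0.370 for fibroblasts. No library was shared between the ventricle and cell fits.

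Isoform use changed in 1205 of 3916 tested genes in cardiomyocytes (1968 of 11170 isoforms). The largest change was that of the protein-coding isoform Synpo-211 of synaptopodin, an actin-associated protein (chromosome 18, 60759860 to 60783890). Its share of the gene's FPKM rose from 1.30% (mean, n = 2) to 75.9% and 84.7%, a log2 ratio change of 6.22 ± 0.26 (SE, limma adjusted p = 1.76e-05). Tnfaip8-203 (chromosome 18, 50179221 to 50250421) rose from 1.33% to 75.4% and 73.0%. Itga6-205 of integrin alpha 6, annotated as a processed transcript, rose from 11.1% to 80.1% and 85.9%, and Dcakd-203, annotated as a retained intron, from 3.37% to 74.5% and 69.0%. Ldhd-203, also annotated as a retained intron, fell from 95.5% to 24.4% and 18.7%. In later fibroblasts, the share of Synpo-211 was 0% and 0.158% and that of Tnfaip8-203 0.390% and 0.377%.

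Vesicular trafficking and splicing regulator genes were examined as lists. In cardiomyocytes, 20 of 49 trafficking genes (40.8%) changed isoform use, against 30.6% of other genes (two-sided Fisher's exact test, p = 0.160, adjusted p = 0.319 over 6 tests). Snap23-203, of a protein of membrane fusion, rose from 5.71% to 38.8% and 46.2% (log2 ratio change 3.35 ± 0.28, SE). Ap2a1-203, of the clathrin adaptor, rose from 30.1% to 68.2% and 63.9% (2.08 ± 0.21). Gopc-201 fell from 84.9% to 46.2% and 57.9%. Arfgap2-201 rose by 23.6 percentage points, Rab11a-208 by 20.8, Vamp2-201 by 17.4, Rab11fip3-203 by 17.1 and Ap2b1-201 by 16.9. Among splicing regulators, 14 of 26 (53.8%) changed against 30.6% of other genes (Fisher's exact test, p = 0.0170, adjusted p = 0.102). Srsf3-201 (-22.6 points), Tra2b-206 (-15.6) and Hnrnpu-206 (-14.4) fell, all annotated as targets of nonsense-mediated decay. Hnrnph1-202 fell from 26.4% to 7.11% and 6.23%, and Tial1-201 changed by -18.9 points. Hnrnph2-202 rose by 18.4 points, Hnrnpr-204 by 16.9 and Khdrbs1-201 by 12.1.

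In fibroblasts, 306 of 3916 genes changed isoform use (437 isoforms). Slc8a1-202, of the sodium-calcium exchanger, rose from 5.97% (mean, n = 2) to 84.2% and 85.0%, a log2 ratio change of 4.59 ± 0.19 (SE, limma adjusted p = 0.000103). Cmc2-206, annotated as a target of nonsense-mediated decay, rose from 15.3% to 72.0% and 63.6%. Arhgap24-205 fell from 85.2% to 4.2% and 9.05%, Myl4-202 from 67.9% to 6.72% and 15.9% and Tk1-201 of thymidine kinase from 61.7% to 9.92% and 11.7%. Slc8a1 and Myl4, which cardiomyocytes express, were measured in neonatal fibroblast libraries with cardiomyocyte markers at 10.1% and 8.80% of their cardiomyocyte level. Of 49 trafficking genes, 6 changed (Fisher's exact test, p = 0.274, adjusted p = 0.412). Among them were Stx5a-201 (17.8 points), Golga2-203 (-15.5), Kif1b-201 (-14.0) and Cav1-201 (-11.9). In cardiomyocytes, Kif1b-201 changed by 12 and Cav1-201 by 15.3 points. Of 26 splicing regulators, 4 changed (Fisher's exact test, p = 0.141, adjusted p = 0.319). These were Srsf5-206 (-18.4 points), Hnrnph1-201 (18.4), Celf1-205 (-18.3) and Hnrnph2-203 (-14.9). The count of 306 was 105 and 166 without the second and the first neonatal fibroblast library, 203 without PN28, and 202 and 202 without the first and second neonatal cardiomyocyte library. It was 97 at a change of at least 20 points, where the cardiomyocyte count was 410, and 173 with a gene mean FPKM of at least 20, where it was 520.

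In ventricles, 75 of 3627 genes had a trend in isoform use (106 of 9910 isoforms). Tnfaip8-203 rose from 4.71% at E17 to 12.2%, 60.8%, 87.6% and 84.6%, and Synpo-211 from 2.22e-05% to 8.11%, 50.4%, 70.2% and 69.8%. Ift81-203, annotated as a retained intron, rose from 1.13% to 62.9% at PN90, and Entpd5-207, also annotated as one, fell from 71.3% to 10.3%. Tnnt2-204, an isoform of cardiac troponin T (chromosome 1, 137737452 to 137748837), fell from 78.3% at E17 to 51.1%, 19.5%, 11.9% and 9.93%. Its slope was -1.30 ± 0.16 log2 units per stage (SE, limma adjusted p = 0.0416). In cardiomyocytes, Tnnt2-204 fell from 59.8% and 53.3% to 11.2% and 8.88%, and in fibroblasts from 53.0% and 58.0% to 15.7% and 21.0%. The neonatal fibroblast libraries held cardiomyocyte markers at 10.1% and 8.80% of their cardiomyocyte level. The fall in fibroblasts may therefore be one of cardiomyocyte RNA. Of 48 trafficking genes and 28 splicing regulators, limma called 0 in ventricles, where 1935 of all isoforms had an unadjusted p below 0.05. The count of 75 was 0 without E17, PN1, PN28 or PN90, 147 without PN10, and 10 with 0.1 in place of 0.5 added to the ratio. Of isoforms called in ventricles, 27 rose and 20 fell in cardiomyocytes too, where independent lists would share 4.26 and 2.83, and 0 went the opposite way. With fibroblasts, 3 and 4 were shared, where independent lists would share 0.684 and 0.750, and 2 went the opposite way.

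**Figure D4:**
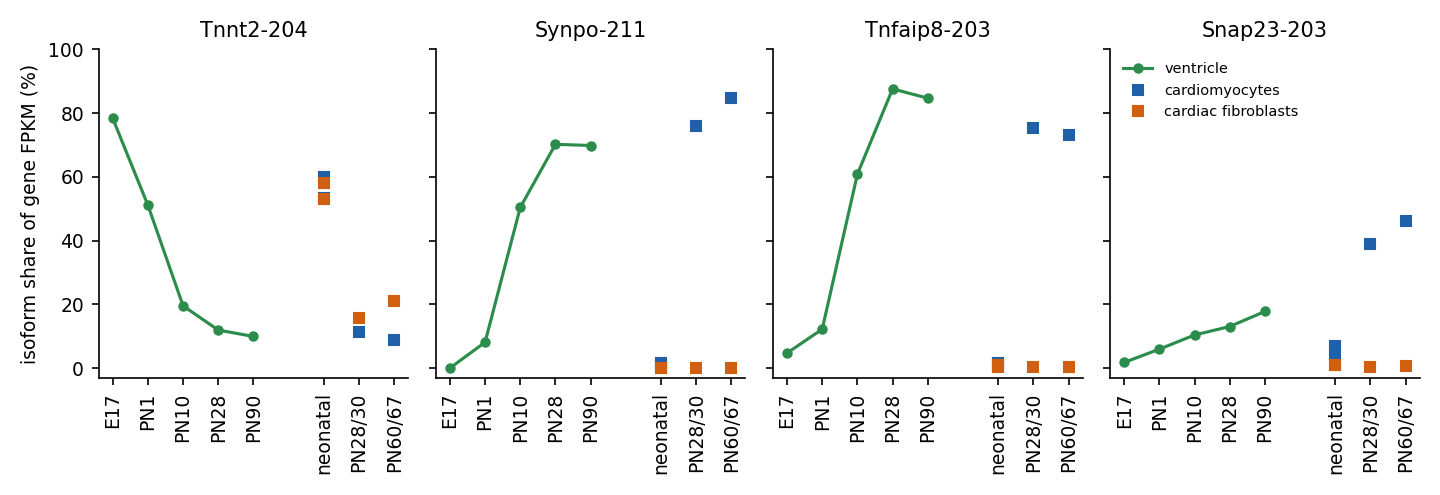
Share of an isoform in the FPKM of its gene (%) in the 5 ventricle stages (joined by lines) and in the cardiomyocyte and cardiac fibroblast libraries (squares, 1 per library). Tnnt2-204 fell in all 3 series, Synpo-211 and Tnfaip8-203 rose in ventricles and cardiomyocytes, and Snap23-203 rose in cardiomyocytes and did not pass the test in ventricles. The fall of Tnnt2-204 in fibroblasts may be one of cardiomyocyte RNA in the neonatal fibroblast libraries.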

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

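Of the tests in this part, the one on oxidative phosphorylation after subtraction of the cardiomyocyte share was set before its result was seen, and the other tests, with the subtraction itself, were chosen after the results were seen.

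The stage change differed between cardiomyocytes and fibroblasts for 7124 genes by the limma test of the difference itself. Of these, 1529 were called in opposite directions, 854 up in cardiomyocytes and down in fibroblasts and 675 the other way. These counts were made without subtraction of the cardiomyocyte share, and no count with it is given here. The largest differences of log2 change were those of Ckmt2 (7.56 ± 0.27, SE), Myl3 (7.40 ± 0.18) and Myl2 (6.93 ± 0.23), and those of Il6 (-10.96 ± 0.46), Cxcl2 (-9.09 ± 0.52) and Cxcl3 (-8.85 ± 0.60). With the cardiomyocyte share subtracted from the fibroblast libraries, the differences were 5.79 for Ckmt2, 5.28 for Myl3 and 6.07 for Myl2. The changes of these genes in cardiomyocytes alone were 5.55, 2.06 and 1.53, so little of the Ckmt2 difference then came from a fall in fibroblasts. Ckmt2 changed from 51.1 to 2607 and 2238 FPKM in cardiomyocytes and from 4.64 to 0.327 and 0.448 in fibroblasts. Cxcl2 changed from 36.9 to 1.17 and 4.34 FPKM in cardiomyocytes and from 102 to 5673 and 4512 in fibroblasts.

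Genes that differed between the cell types were also counted, in a fit without stage, over splits of the 8 libraries into 4 and 4. Of 35 splits, 1 called as many genes, which was the split by cell type itself (4542 genes, against at most 594 in any other). Libraries of the same class correlated closely (Spearman's rho 0.993, 0.984, 0.989 and 0.963). Splits that part them are therefore not equal alternatives, and this rank alone cannot exclude chance. The RNA extraction kit also differed between the cell types. The stage changes compared 2 libraries with 2 and were not part of the test by splits.

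Cardiomyocyte genes and oxidative phosphorylation genes fell in fibroblasts, and cardiomyocyte RNA carried into the neonatal fibroblast libraries may account for it. The ratio of neonatal fibroblasts to neonatal cardiomyocytes was taken over 206 falling genes that were at least 50-fold higher in later cardiomyocytes than in later fibroblasts. It had a median of 10.9%, and its 75th percentile was 1.83 times its 25th, within the 2-fold bound set for 1 common source. The genes were chosen for a called fall, so genes very low in neonatal fibroblasts could hardly enter, and the narrow span is partly set by this choice. After the share was subtracted, the median of 51 oxidative phosphorylation genes moved from -0.69 to -0.08, at a distance of -0.0949 from the median of all genes, just inside the bound of 0.1. The share of Tnnt2-204 in neonatal fibroblasts (53.0% and 58.0%) was near that in neonatal cardiomyocytes (59.8% and 53.3%). A change of fibroblasts with age in the same genes stays open and was not tested.

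Complement, chemokine and cytokine genes rose in later fibroblasts, for which a response to isolation, RNA of macrophages and a change with age were considered. A response of complement genes to isolation cannot be told apart, since 0 of 6 that rose stood below the lowest fibroblast marker in the ratio of PN28 and PN90 ventricles to later fibroblasts, but their range (6.52% to 35.6%) lay inside that of the markers (3.09% to 45.3%). Of 8 chemokine and cytokine genes that rose, 4 stood below that lowest marker, but 5 stood below the lowest in the ratio of the PN1 ventricle to neonatal fibroblasts too. The 4 were Il6 (0.00038%), Ccl7 (0.028%), Cxcl5 (0.037%) and Ccl8 (1.27%), and the others ranged from 3.74% to 121%. Il6 had a mean of 2914 FPKM in later fibroblasts and of 0.0111 in PN28 and PN90 ventricles. Fibroblasts of every stage were isolated in the same way. A response to isolation would therefore have to differ with age to give the rise of chemokine genes, and it cannot be told apart from a change of fibroblasts with age. In whole ventricles, 9 of 12 complement and chemokine genes rose with stage and 0 fell (median slope 0.56, camera adjusted p = 0.000368, and adjusted p = 0.488 with an estimated correlation). Ventricles hold other cells too, so this does not decide the question for fibroblasts. Macrophage RNA of the kind in the later cardiomyocyte libraries cannot be told apart, since the median ratio of later fibroblasts to later cardiomyocytes was 38.4 over the chemokine and cytokine genes, above the highest of a macrophage marker (24.7), while their lower quartile (7.37) was below it. The complement, chemokine and cytokine genes were chosen for a called rise in later fibroblasts, and the markers were not. The later fibroblast level enters both ratios, so low ventricle ratios and high ratios to cardiomyocytes are partly built in.

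Immediate early and stress genes fell in cardiomyocytes, for which the isolation of neonatal cells, fibroblast RNA and a change with age were considered. Against fibroblast RNA in the neonatal cardiomyocyte libraries as the whole cause, the called members would need a median fibroblast share of 62.4% (lowest 42.7%), while fibroblast markers gave at most 22.8%. The members were chosen for their fall, which favours a high needed share, and a part of the fall from fibroblast RNA is not excluded. Of 11 called members (18 fell with the FPKM as deposited), 9 lay below the 5th percentile of all genes (10.7%) in the ratio of the PN1 ventricle to neonatal cardiomyocytes, with Hmox1 at 541 FPKM in neonatal cardiomyocytes and 3.39 in the ventricle. The members were called for a fall from their neonatal cardiomyocyte level, which is also the denominator of this ratio. Low ratios are therefore partly built in, and other falling genes were not compared. A response to the isolation of neonatal cells could give such ratios, with the limit that ventricle and cell libraries were made with different kits. In whole ventricles, the list had 2 up and 3 down of 18 measured members (median slope -0.02, camera adjusted p = 0.915). A fall of the list with stage was thus not seen there, but the test could miss one, and ventricles hold other cells too. The list had 26 measured members in cells, and the ventricle trend recovered 13% of simulated log2 changes of 1. In the PN1 ventricle, Fosb, Hspa1a and Hspa1b stood at 0.0323, 0.280 and 0.545 FPKM and could hardly fall. The other called members ranged from 1.22 to 33.0 FPKM. Age and isolation method changed together in cardiomyocytes, so a change with age in these cells stays open and was not tested apart from isolation.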

How the results depend on the processing

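The alternatives that subtracted the cardiomyocyte share or left out genes called higher in the other cell type were chosen after seeing the data, and the other tests were planned. No named gene reversed under the scalings, the pseudocount of 0.1 or with 1 library left out, but splits of counts did. With the FPKM as deposited, the rises and falls were 3363 and 4867 in cardiomyocytes in place of 4467 and 3668, 1474 and 4656 in fibroblasts in place of 2382 and 2591, and 1271 and 3445 in ventricles in place of 2212 and 1880. With mitochondrial genes removed, in this order, they were 3003 and 5227, 1489 and 4703, and 1266 and 2889, and the genes higher and lower in cardiomyocytes than in fibroblasts were 3869 and 5586 in place of 4494 and 4781. Among lists, trafficking genes turned in cardiomyocytes, fibroblasts and ventricles, splicing regulators and glycolysis in fibroblasts and smooth muscle markers in ventricles under both scalings. Matrix proteases in fibroblasts and cell cycle genes between the cell types turned with mitochondrial genes removed. A fit of the 4 libraries of a cell type alone gave 3209 fibroblast genes in place of 4973 and 9240 cardiomyocyte genes in place of 8135. The fit of all 8 libraries shared 1 error between the cell types. PN28 and PN60 fibroblasts correlated less (Spearman's rho 0.963) than PN30 and PN67 cardiomyocytes (0.984), and whether this was the cause was not tested. Across cell types, a fit without stage gave 4542 in place of 9275, where stage was left in the error. Leaving out genes called higher in fibroblasts gave 5056 cardiomyocyte genes in place of 8135 (fewer genes tested), 4074 up and 982 down, and leaving out genes called higher in cardiomyocytes gave 3336 fibroblast genes, 2089 up and 1247 down. Both filters use levels averaged over the stages, so a stage change helps decide which genes are kept and the shifts of these splits are partly built in. With the share subtracted, the fibroblast genes were 2388 up and 2096 down, and 9 fibroblast lists passed in place of 16, with glycolysis gained (adjusted p = 0.0417, and adjusted p = 0.614 with an estimated correlation) and 8 lists lost. For the cardiomyocyte markers, which set the share, this followed from the subtraction itself. The lost ones were cardiomyocyte markers, sarcomere, fetal muscle, calcium handling, oxidative phosphorylation, fatty acid oxidation, the tricarboxylic acid cycle and immediate early genes, of which the tricarboxylic acid cycle turned from 1 up and 9 down to 6 up and 2 down, while immediate early genes had 8 up and 0 down both times and a median of 0.43 in place of 0.49. In that setting 4296 fibroblast genes were called in the same direction with and without it, 653 only without, 164 only with it and 24 in opposite directions. Under the estimated correlation, 0, 0 and 0 lists passed in cardiomyocytes, fibroblasts and ventricles.

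For isoforms, a change of 20 points left 410 cardiomyocyte and 97 fibroblast genes, and a gene mean FPKM of 20 left 520 and 173 (fewer genes tested). An offset of 0.1 left 10 ventricle genes, and the cause was not tested.

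With 1 library left out, which assumes that a lone sample varies like the other groups, the counts ranged from 6391 to 9182 for cardiomyocytes, 2769 to 6313 for fibroblasts (lowest without the second neonatal fibroblast library), 5371 to 8053 for the difference of changes, 8382 to 9803 for cell type and 1130 to 4612 for ventricles (lowest without E17, 2345 without PN1 and 2275 without PN28). Isoform counts ranged from 943 to 1237 in cardiomyocytes, 105 to 374 in fibroblasts (lowest without the second neonatal fibroblast library, 166 without the first, 203 without PN28 and 202 without either neonatal cardiomyocyte library) and 0 to 147 in ventricles (lowest without E17, PN1, PN28 or PN90, highest without PN10). Of the tests of named genes with 1 library left out, 505 gave the same call and 7 lost it in cardiomyocytes. In fibroblasts 467 gave the same call, 3 lost and 2 gained one, for cell type 147, 4 and 1, and in ventricles 254, 40 and 1. Under the other alternatives the total counts, though not all of their splits, stayed within 1.5 times. No paired analysis was possible because the replicate numbers were given in deposit order and name no shared animal, litter or day.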

Other observations

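The lists differed in when they moved over the ventricle stages, given here as the median log2(FPKM + 1) of their members at E17, PN1, PN10, PN28 and PN90, with 1 library each and no test of single steps. Cell cycle genes stood at 4.88, 4.13, 2.66, 1.05 and 0.90, so that the largest steps lay between PN1 and PN28. Oxidative phosphorylation genes stood at 7.80, 8.51, 8.84, 9.67 and 9.71. Glycolysis genes, which split in direction, stood at 6.77, 5.59, 5.69, 6.33 and 6.18. Fibroblast markers stood at 5.46, 5.74, 6.30, 5.64 and 4.89, highest at PN10. Erythroid markers, of red blood cells, stood at 7.66, 3.49, 4.64, 3.86 and 3.38, highest at E17.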
